A study of Bos taurus with 5 samples.

How the data were processed

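Leukocytes from peripheral blood of 5 cattle populations were sequenced, with 1 library for each population. Per the labels' protocols, white cells came from a buffy coat washed with red cell lysis buffer, total RNA was extracted with Trizol, poly(A) RNA was selected with oligo-dT beads and fragmented, and cDNA was primed at random and sequenced from both ends on an Illumina HiSeq instrument. The protocol names no step that marks the strand of a transcript. Per the submitters' processing notes, TopHat2 2.0.9 and Cufflinks 2.2.1.0 were used. The genome build, the annotation and the settings of these tools are not given in the sources used here.

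The authors deposited FPKM values, fragments per kilobase of transcript scaled to the fragments mapped in a library, for 72812 assembled transcripts, in tables whose columns are those of a Cuffdiff comparison per the file headers. One table compares the 5 populations in 10 pairs, and the value of a library was identical in all 4 comparisons it enters. The other table compares the crossbred with the purebred populations, and its deposited values were close to the means of the single libraries, with median ratios of 0.999 for the purebreds and 1.01 for the crossbreds. The authors' tables also hold a p-value and a q-value for each transcript and comparison, and the transcripts they mark as significant are those tested at a q-value of at most 0.05. The smallest p-value in the deposited pairwise table is 5e-05. FPKM values divide reads between the transcripts of a locus and between near-identical copies by a model, so an exact 0 can be a failed estimate. Of the kept loci, 66 were listed at 0 in N, 110 in H, 101 in 75C, 97 in 50CSN and 110 in 50CSH, 225 in at least 1 library, and 212 of the 225 had a single transcript. A locus at 0 is therefore described as listed at 0, and no fold is given against it.

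The transcripts were summed over the 31898 loci of the authors' assembly, and 13871 loci with a mean of at least 1 FPKM over the 5 libraries were kept, 11666 with an Ensembl transcript ID and 2205 without. Values were compared as log2(FPKM + 1), a scale that understates the change of low loci. A pair of libraries was described by the number of loci at least 2-fold apart, with no test, since each population has 1 library. The crossbred and purebred libraries were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment over the kept loci. In simulated data with the spread of each locus as observed, 200 of 13871 loci were given a known difference. They were drawn from loci with a mean log2(FPKM + 1) above 2. Limma recovered 64 percent of those changed 2-fold and 90 percent of those changed 4-fold, with 8 false calls in each run. The simulated values had independent normal noise, with no listed zeros and no shift of a whole library. The recovery therefore does not extend to low loci or to loci listed at 0. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Coordinates are those of the deposited tables, counted from 1.

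Loci were counted in windows of 1 Mb, and the 5 windows with the most loci at least 2-fold apart were compared with 1000 shuffles of the loci over their positions. Windows, chromosome sets for camera, and the number of annotated loci in a window of 1 Mb centred on a locus were chosen after the data were seen. That number includes the locus itself where it is annotated. The trend of each library with that number was also removed by a lowess curve over a fraction of 0.3 of the loci.

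Depth is limited to a relative estimate. At loci with a single transcript and values in the lowest 30 percent, the most frequent ratio between a library and H was taken as the ratio of what 1 read is worth. No count of reads and no interval for counting error can be given from these tables.

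The rule for named loci, set before the data were examined, took the 12 highest and 12 lowest loci for H against N and for 50CSH against 50CSN, the 12 highest and 12 lowest without overlap between crossbreds and purebreds, the 4 farthest above and 4 farthest below both purebreds for each crossbred, members of fixed gene lists, and loci past the adjusted threshold. It asked for a gene symbol. None of the 31460 Ensembl transcript IDs could be matched to the reference table of gene names used here, which carries no Ensembl IDs, so an Ensembl ID stood in for the symbol. For the same reason the 28 gene lists fixed beforehand, which covered leukocyte types, erythroid and platelet markers and immune pathways, were not tested. Loci from the rule were named in part, and loci with an Ensembl ID and above 0 in all libraries were ranked in addition.

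Alternatives set beforehand were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, values per transcript, limma without a trend and with robust fitting, an adjusted p of 0.1, a margin of 2-fold, a purebred difference of 4-fold, and the removal of each library in turn. Alternatives added after the data were seen were loci above 0 in all 5 libraries, loci with an Ensembl transcript ID, and removal of the density trend.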

Results

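Peripheral blood leukocytes of cattle were profiled by RNA sequencing in 5 populations, with 1 library for each. The purebred populations were labelled N and H. The crossbred populations descended from Holstein, a dairy breed, and native cattle of Iran. 50CSN carried 50 percent of each breed through a native sire and a Holstein dam, 50CSH carried 50 percent of each through a Holstein sire and a native dam, and 75C carried 75 percent Holstein and 25 percent native ancestry. The labels do not spell out the letters N and H, and they do not say whether a library came from 1 animal or from several. No difference between 2 populations has a replicate check, and the p-values of the pooled comparison measure only the spread among these 5 libraries. The deposited values were FPKM per transcript, and the sum over the transcripts of an assembled locus was compared for the 13871 loci with a mean of at least 1 FPKM. The summed FPKM was 735252 in N, 733855 in H, 843353 in 75C, 852903 in 50CSN and 789089 in 50CSH. Read totals were not given in the sources used here, and the most frequent ratios to H among low values of loci with a single transcript put the depth relative to H at roughly 1.19 for N, 0.937 for 75C, 1.15 for 50CSN and 1.02 for 50CSH. Transcripts of the mitochondrial chromosome took 6.41 percent of the summed FPKM in N, 5.67 percent in H, 5.70 percent in 75C, 6.03 percent in 50CSN and 5.82 percent in 50CSH. Loci under 300 nt without an Ensembl ID took 15.5 percent in N, 14.2 percent in H, 18.3 percent in 75C, 12.3 percent in 50CSN and 13.2 percent in 50CSH. Genes were identified by Ensembl transcript ID or by position alone, and the files do not pair these IDs with gene names, so loci are described by chromosome and position as deposited. The genome build is not given in the sources used here. The span given for a locus is that of a group of neighbouring transcripts and can hold several loci. Markers of leukocyte types could not be read for the same reason, so a difference in cell composition between the libraries was not measured.

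The purebred libraries were compared to ask how the parental populations differ. A block of chromosome 23, between 28 and 29 Mb, held the most lower loci of any 1 Mb window. Of its 39 kept loci 7 were at least 2-fold lower in H than in N and 1 was higher. The median log2 difference over the 39 was -0.09. No window held as many lower loci in any of 1000 shuffles of the loci over their positions, where the highest count was 5. The 7 had a median span of 213042 nt, the length of a span in this block that 13 kept loci share. Loci that share reads are not independent, as the shuffles assume, so the shuffles cannot show 7 separate changes. Of the 7, 5 had a single transcript and 4 were listed at 0 in at least 1 library. Chromosome 23 of cattle carries the major histocompatibility complex, whose products present antigens to T cells, but the files do not say whether these loci belong to it. One locus in the span from 28472237 to 28685278 was at 243 FPKM in N and 292 FPKM in 50CSN and was listed at 0 in H, 75C and 50CSH. Another locus of chromosome 23, in the span from 27808462 to 27884733, was listed at 0 in N and stood at 3261 FPKM in H, 715 FPKM in 75C, 690.2 FPKM in 50CSN and 1459 FPKM in 50CSH. Between 31 and 32 Mb of the same chromosome, 4 of 41 loci were higher in H and 5 were lower.

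Across the genome 202 loci were at least 2-fold higher in H than in N on the log2(FPKM + 1) scale and 258 were at least 2-fold lower. The rule for named loci took 12 higher and 12 lower, and 23 of these 24 were listed at 0 in at least 1 library. Loci with an Ensembl ID and above 0 in all 5 libraries were therefore ranked as well, a choice made after the values were seen. Highest in H by that ranking was a locus of chromosome 18 from 46718166 to 46737669, at 37.2 FPKM in H and 16.2 FPKM in 75C, against 1.65 FPKM in N, 2.22 FPKM in 50CSN and 1.92 FPKM in 50CSH. On chromosome 11, from 51004921 to 51007327, a locus was at 103 FPKM in H and 11.3 FPKM in N. On chromosome 5, from 117480208 to 117486671, the level was 51.1 FPKM in H and 7.42 FPKM in N. Lowest in H was a locus of chromosome 9 in the span from 40676200 to 40949439, at 0.161 FPKM, against 74.8 FPKM in N and 150.6 FPKM in 50CSH. A locus of chromosome 14 from 64829665 to 64830135 was at 20.3 FPKM in N and 0.187 FPKM in H, and the crossbred libraries lay at 4.99 FPKM in 75C, 6.91 FPKM in 50CSN and 22.4 FPKM in 50CSH. The authors' deposited table calls, between H and N, 30 transcripts, 10 of them higher in H, and 18 of the 30 were listed at 0 in one of the 2 libraries.

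The reciprocal crosses have the same breed shares and opposite sire breeds, so their comparison addresses the direction of the cross. At a locus of chromosome 2 from 97468246 to 97470058 the level was 179.9 FPKM in 50CSN and 0.819 FPKM in 50CSH, with 133 FPKM in N, 10.5 FPKM in H and 12.8 FPKM in 75C. On chromosome 15, from 28237704 to 28295247, a locus was at 21.9 FPKM in 50CSN and 2.84 FPKM in 50CSH, and under 1 FPKM in the other 3 libraries. Higher in 50CSH were a locus of chromosome 13 in the span from 67902547 to 67917809, at 38.5 FPKM against 0.702 FPKM in 50CSN, and a locus of chromosome 7 from 13646929 to 13647801, at 120.4 FPKM against 24.3 FPKM. On chromosome 10, between 24 and 25 Mb, 5 of 18 loci were at least 2-fold lower in 50CSH and 2 were at least 2-fold higher. All 5 lower loci had a single transcript, 4 had no Ensembl ID and 2 were listed at 0 in at least 1 library. The highest count of lower loci in any shuffle was also 5. The cattle T cell receptor alpha and delta genes lie on chromosome 10, and the files do not say whether these loci are among them. In the block of chromosome 23 between 28 and 29 Mb, 4 of 39 loci were lower in 50CSH, 3 of them listed at 0 in at least 1 library, and 2 were higher, and shuffles reached up to 5 lower loci in a window. One of them was at 1739 FPKM in N, 1057 FPKM in H, 1583 FPKM in 75C and 312 FPKM in 50CSN, and was listed at 0 in 50CSH. In total 174 loci were at least 2-fold higher in 50CSH and 217 were lower. Of the 24 loci taken by the rule, 22 were listed at 0 in at least 1 library. The authors' deposited table calls 17 transcripts, 11 of them higher in 50CSH, and 13 of the 17 were listed at 0 in one of the 2 libraries.

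The 75C library was set against each 50 percent cross, which carries a smaller share of Holstein ancestry. Chromosome 5 carried 2 blocks that were higher in 75C than in 50CSH. Between 109 and 110 Mb, 8 of 18 loci were at least 2-fold higher and none was lower, with a median fold of 2.83 among the 8, and no shuffle gave more than 7 in a window. Between 9 and 10 Mb, 7 of 10 loci were higher, with medians of 4.86 FPKM in 75C and 1.28 FPKM in 50CSH. Over the same loci the medians were 5.17 FPKM in H and 7.84 FPKM in 50CSN in the first block, and 1.64 FPKM in H and 3.04 FPKM in 50CSN in the second. The loci were chosen for a high value in 75C, so these medians cannot place the other libraries by their Holstein share. On chromosome 19, between 44 and 45 Mb, 5 of 24 loci were higher in 75C than in 50CSN, 3 of them listed at 0 in at least 1 library, and 6 were higher in 75C than in 50CSH, 4 of them so listed. Neither count exceeded the highest of the shuffles, 6 and 7, nor did that between 9 and 10 Mb of chromosome 5. The shuffles treat neighbouring loci as independent, which loci that share reads are not. In total 308 loci were higher in 75C than in 50CSN and 189 were lower, and 352 were higher in 75C than in 50CSH and 148 were lower. After quantile normalization the split was 259 higher and 215 lower against 50CSN, and 293 higher and 174 lower against 50CSH. The 75C library also held the largest share of the 5 in short loci without an Ensembl ID, 18.3 percent of the summed FPKM. The authors' deposited table calls 31 transcripts between 75C and 50CSN, and 21 between 75C and 50CSH in the same table of the authors.

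Each crossbred library was also set against each purebred library. The 50 percent crosses had more loci below than above either purebred: 561 lower and 252 higher for 50CSN against N, 507 and 298 for 50CSN against H, 588 and 205 for 50CSH against N, and 578 and 240 for 50CSH against H. After quantile normalization the split against N was 457 lower and 323 higher for 50CSN, and 475 lower and 287 higher for 50CSH. The 75C library had 364 loci lower and 290 higher than N, and 259 lower and 229 higher than H. All 8 loci that the rule took for each crossbred were single transcripts listed at 0 in at least 1 library. Among these, a locus of chromosome 19 in the span from 39265919 to 39591013 was at 3189 FPKM in 75C and listed at 0 in the other 4 libraries. A locus of chromosome 3 in the span from 1123187 to 1302891 was at 514 FPKM in 50CSN and 139.6 FPKM in 50CSH and listed at 0 in N, H and 75C. On chromosome 25, in the span from 28665726 to 28718409, a locus was at 30.4 FPKM in N, 38.6 FPKM in H and 45.2 FPKM in 75C and listed at 0 in both 50 percent crosses. The authors' deposited table calls between 28 transcripts, for 75C against H, and 69 transcripts, for 75C against N, in these 6 comparisons.

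**Figure D1:**
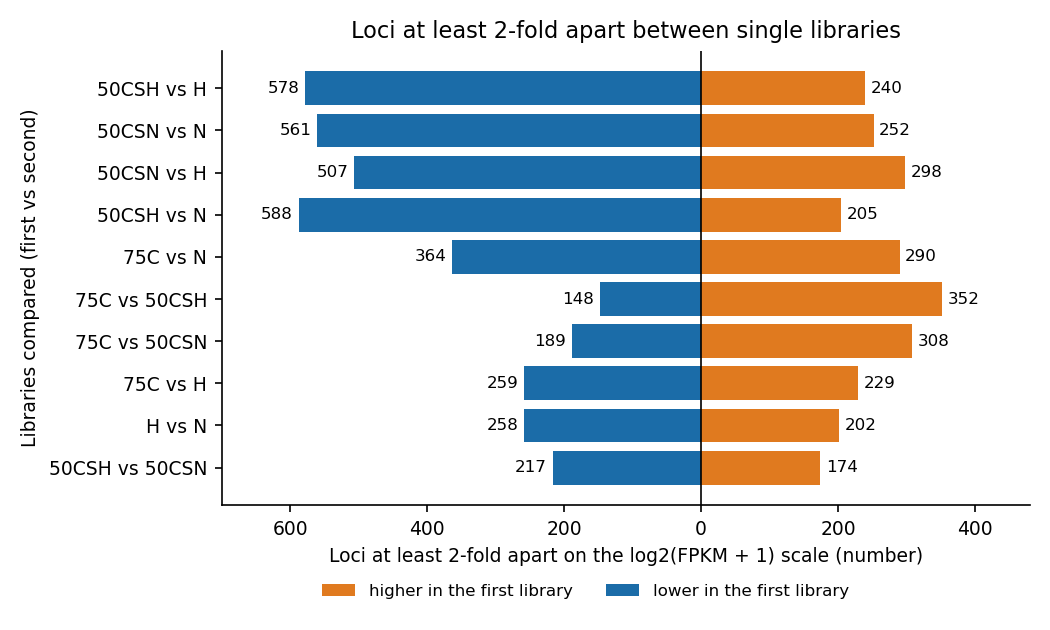
Number of loci at least 2-fold apart on the log2(FPKM + 1) scale for each pair of libraries, with loci higher in the library named first to the right and loci lower in it to the left. The 4 comparisons of a 50 percent cross with a purebred have the longest bars to the left, from 507 to 588 loci.

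The pooled comparison of 3 crossbred with 2 purebred libraries asks what sets crossbred animals apart, with different populations standing in for replicates. By limma with Benjamini-Hochberg adjustment, 4 loci passed an adjusted p of 0.05, and all 4 fell in the crossbreds, 3 of them to a listed 0 that can be a failed estimate. On chromosome 12, in the span from 14459918 to 14463902, the locus of ENSBTAT00000060235 was at 65.1 FPKM in N and 44.1 FPKM in H and listed at 0 in all 3 crossbreds (limma adjusted p = 0.0017). On unplaced sequence Un.004.2, in the span from 1668325 to 1810570, a locus was at 21.0 FPKM in N and 26.3 FPKM in H and listed at 0 in the crossbreds (limma adjusted p = 0.0017). On chromosome 19, in the span from 8734352 to 8883076, a locus was at 5.56 FPKM in N and 6.71 FPKM in H and listed at 0 in the crossbreds (limma adjusted p = 0.030). The locus on chromosome 18 from 57090258 to 57143002, with 17 transcripts and 4 Ensembl IDs including ENSBTAT00000022604, was above 0 in every library. It stood at 31.0 FPKM in N and 29.2 FPKM in H, against 8.25 FPKM in 75C, 6.38 FPKM in 50CSN and 7.18 FPKM in 50CSH, a log2 difference of -1.92 with a standard error of 0.12 (limma adjusted p = 0.032). With the 13646 loci above 0 in all 5 libraries, a selection made after the data were seen, its adjusted p by limma was 0.063 and no locus passed. At an unadjusted p of 0.05 limma gave 3014 loci, 1646 lower and 1368 higher in the crossbreds. By chance 693.5 would be reached if the libraries of each group were true replicates. At that threshold 50CSN and 50CSH against the rest gave 2645 by limma. The remaining splits of the 5 libraries into 3 and 2 gave 189 to 652. The locus listed at 0 on chromosome 19 did not pass with a pseudocount of 0.1 (limma adjusted p = 0.11). Nor did it pass without 75C, without 50CSN or without 50CSH (limma adjusted p = 0.073, 0.094 and 0.15). A permutation of 3 against 2 libraries cannot go below an exact p of 0.1. Other splits of the 5 libraries into 3 and 2 reached similar counts past the adjusted threshold by limma. These were 7 for 50CSN and 50CSH against the rest, 6 for N and 75C, 5 for N and 50CSN, and 5 for H and 50CSH. The split of 75C and 50CSH gave 4 and the remaining splits 1 or 0. The count of 4 therefore does not set the crossbreds apart.

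**Figure D2:**
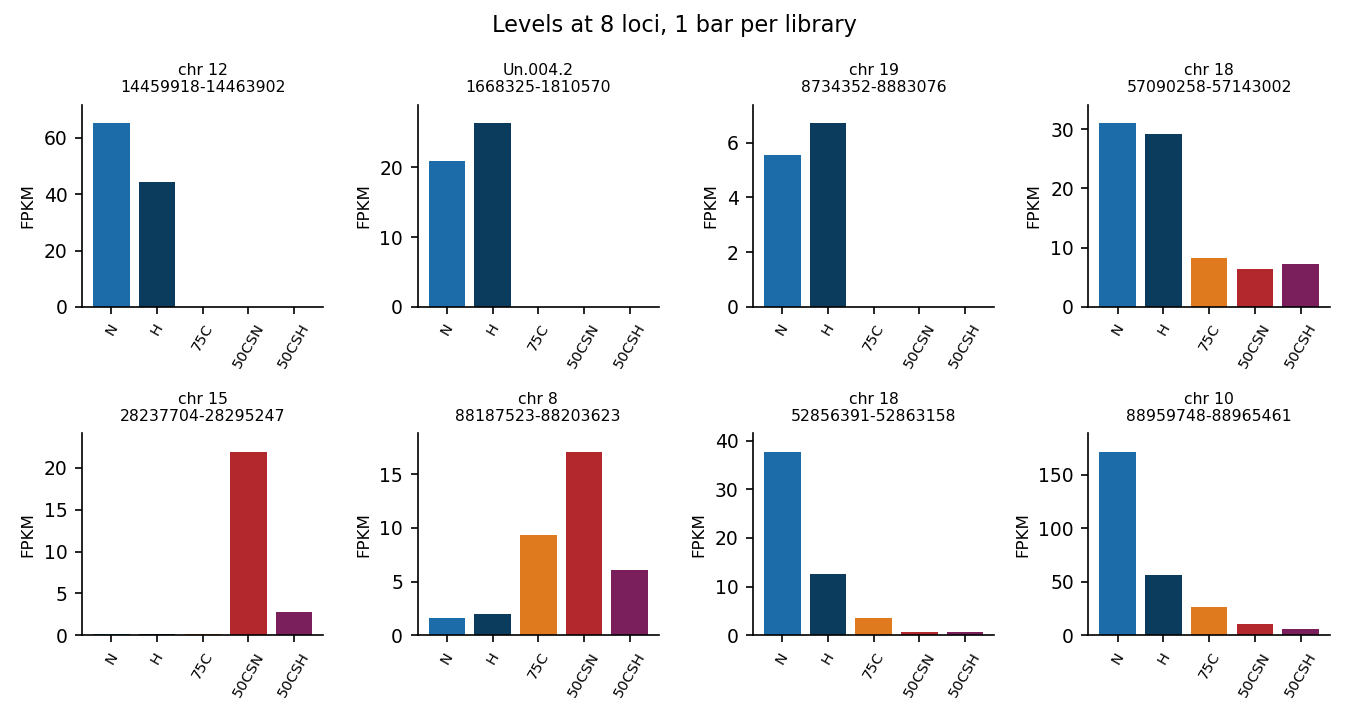
FPKM of 8 loci, with 1 bar for each library and a separate vertical scale for each locus. The upper row holds the 4 loci past an adjusted p of 0.05 by limma, of which 3 are listed at 0 in all crossbreds, and the lower row holds loci above 0 everywhere whose crossbred values all lie above, at left, or below, at right, both purebred values.

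Of the 24 loci without overlap that the rule took for this comparison, 8 were listed at 0 in at least 1 library, 3 of the loci past the threshold among them. The rest of the 24 did not pass. A locus of chromosome 8 from 88187523 to 88203623, ENSBTAT00000015694, was at 1.59 FPKM in N and 2.03 FPKM in H, against 9.31 FPKM in 75C, 17.1 FPKM in 50CSN and 6.13 FPKM in 50CSH (limma adjusted p = 0.12). A locus of chromosome 28 from 41512307 to 41514775, ENSBTAT00000046544, was at 3.20 FPKM in N, 5.73 FPKM in H, 9.06 FPKM in 75C, 20.02 FPKM in 50CSN and 10.8 FPKM in 50CSH (limma adjusted p = 0.15). Lower in the crossbreds was a locus of chromosome 10 from 88959748 to 88965461, at 171.6 FPKM in N, 56.4 FPKM in H, 26.2 FPKM in 75C, 10.3 FPKM in 50CSN and 5.75 FPKM in 50CSH (limma adjusted p = 0.13). A locus of chromosome 18 from 52856391 to 52863158 was at 37.7 FPKM in N and 12.6 FPKM in H, against 3.60 FPKM in 75C, 0.792 FPKM in 50CSN and 0.80 FPKM in 50CSH (limma adjusted p = 0.11). Within the same span of chromosome 19 that held a locus listed at 0 in the crossbreds, another locus was at 169 FPKM in N and 145 FPKM in H, against 304 FPKM in 75C, 420.3 FPKM in 50CSN and 450.5 FPKM in 50CSH (limma adjusted p = 0.11). By chromosome, a division chosen after the data were seen, no set of loci passed an adjusted p of 0.05 in camera. With the preset correlation the smallest adjusted p was that of chromosome 25, with a median log2 difference of -0.11 over 486 loci (camera adjusted p = 0.077 with a preset correlation and adjusted p = 0.92 with an estimated correlation). With an estimated correlation the smallest was 0.70 (camera adjusted p), for sets that include chromosome 1 and chromosome 6, with median log2 differences of 0.04 and 0.07. The authors' deposited table calls 347 transcripts between the pooled crossbred and purebred populations, 114 higher and 233 lower in crossbreds. Of these calls of the authors' deposited table, 313 had all 3 crossbred values on one side of both purebred values. The calls were made for that difference, so this number does not test them. Of all 26826 transcripts with a mean of at least 1 FPKM, 15.7 percent had all 3 crossbred values above both purebred values and 19.9 percent below. None of the 4 loci past the adjusted limma threshold was among the calls of the authors' deposited table.

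The level of a locus relative to the mean of the 5 libraries also went with how many annotated loci lay around it, rising with that number in N and H, falling in the 50 percent crosses and changing little in 75C. Loci were put in 5 groups ordered by that number, counted in a window of 1 Mb centred on the locus. In the group with the fewest, a median of 6 annotated loci, the median log2 difference of crossbreds from purebreds was 0.05. There N lay at -0.03 from the mean of the 5 libraries, H at -0.03, 75C at 0.01, 50CSN at 0.02 and 50CSH at 0.03. In the group with the most, a median of 42, the difference of crossbreds from purebreds was -0.11. In that densest group N stood 0.09 above the mean on the log2 scale, H stood 0.04 above and 75C 0.04 above, while 50CSN was at -0.10 and 50CSH at -0.06.

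**Figure D3:**
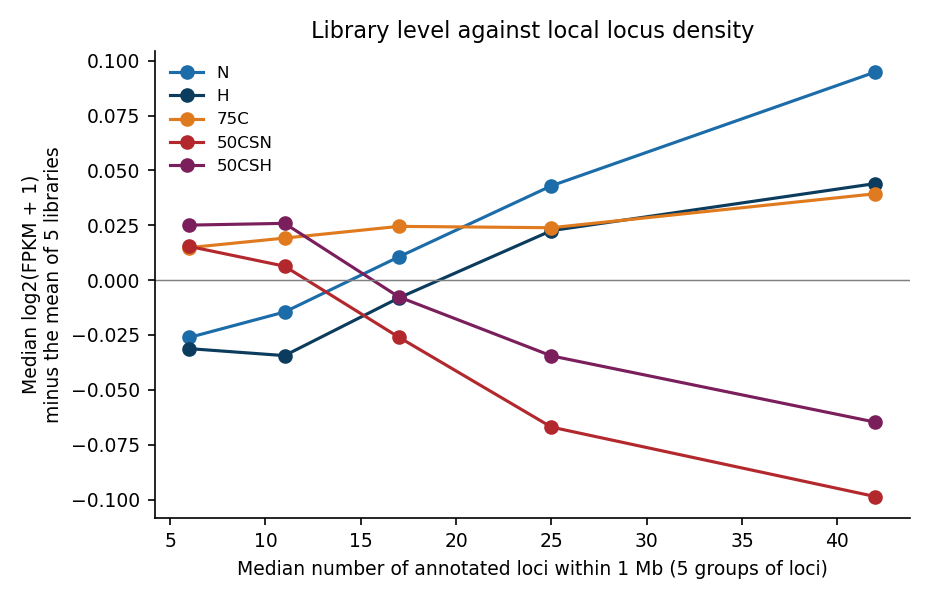
Median log2(FPKM + 1) of each library minus the mean of the 5 libraries, for 5 groups of loci ordered by local locus density. The horizontal axis, labelled as within 1 Mb, is the median number of annotated loci in a window of 1 Mb centred on each locus. The lines of the 50 percent crosses fall to -0.10 and -0.06 in the densest group, where N, H and 75C lie above 0.

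Loci outside the range of the purebreds were counted to describe levels in the crossbreds that are not intermediate. In 44 loci all 3 crossbred values lay at least 1.5-fold above both purebred values, and in 196 they lay at least 1.5-fold below. Without a margin 21.0 percent of the loci lay above and 22.3 percent below, where the order of 5 libraries gives 10 percent in each direction by chance. Between crossbreds and purebreds 6006 loci did not overlap. Between the 50 percent crosses and the other 3 libraries 5632 did not, a similar excess. In the remaining splits of the 5 libraries into 3 and 2, 1382 to 2656 loci did not overlap. The 50 percent crosses are themselves crossbreds, so these counts cannot tell an excess of all crossbreds from one of the 50 percent crosses. On chromosome 10 between 23 and 24 Mb, 4 of 20 loci had a mean at least 2-fold higher in the crossbreds, with medians of 4.46 FPKM in N, 1.89 FPKM in H, 12.3 FPKM in 75C, 10.05 FPKM in 50CSN and 15.8 FPKM in 50CSH. One of them, from 23501758 to 23502470, was at 3.75 FPKM in N, 13.7 FPKM in H, 30.9 FPKM in 75C, 17.7 FPKM in 50CSN and 24.5 FPKM in 50CSH. On chromosome 18 between 62 and 63 Mb, 5 of 31 loci had a mean at least 2-fold lower in the crossbreds, with medians of 11.2 FPKM in N, 8.43 FPKM in H, 5.43 FPKM in 75C, 4.27 FPKM in 50CSN and 3.11 FPKM in 50CSH. Neither count exceeded the highest of the shuffles, 5 and 7. Leaving out a crossbred can only raise the count, since fewer libraries must then lie outside: from 240 it went to 742 without 75C, 164 above and 578 below, to 357 without 50CSN and to 343 without 50CSH.

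The position of the crossbreds between the purebreds was read at the 460 loci at least 2-fold apart between H and N, where 0 is the level of N and 1 that of H. The median position was 0.674 for 75C (95 percent interval 0.592 to 0.731), 0.504 for 50CSN (0.454 to 0.595) and 0.519 for 50CSH (0.469 to 0.595). The intervals come from order statistics over loci, which are not independent replicates. In 61.9 percent of 431 loci 75C lay farther toward H than 50CSN did (exact binomial 95 percent interval 57.2 to 66.6). In 61.3 percent of 421 loci it lay farther toward H than 50CSH did (56.4 to 66.0). Values of 75C beyond H count here as well, and loci with equal values were left out. At 63.0 percent of the 460 loci 75C lay between the purebreds. Positions near the middle also arise where ancestry does not order the libraries: at the 391 loci at least 2-fold apart between 50CSH and 50CSN, with 50CSN at 0, the medians were 0.422 for N, 0.569 for H and 0.520 for 75C. Medians as far from the middle as that of 75C, or against the order of ancestry, arose with other ends. Between N, at 0, and 75C, at 1, H lay at 0.561, below 50CSN at 0.645 and 50CSH at 0.659, and between H, at 0, and 75C, at 1, 50CSN lay at 0.729 and 50CSH at 0.769.

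**Figure D4:**
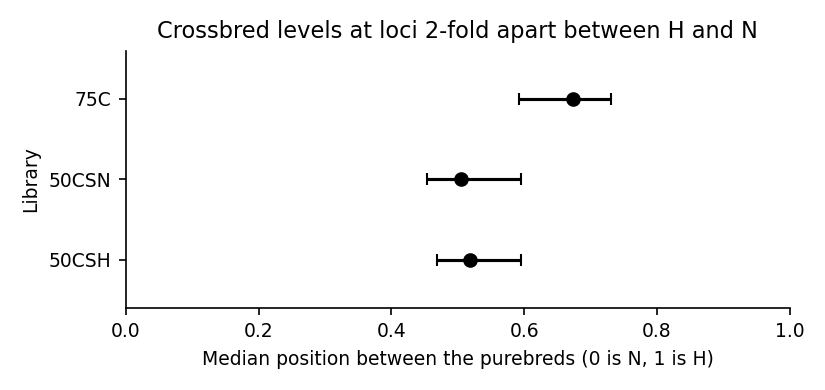
Median position of each crossbred library between N, at 0, and H, at 1, over the 460 loci at least 2-fold apart between H and N, with bars for the 95 percent interval from order statistics. 75C lies at 0.674 and the 50 percent crosses at 0.504 and 0.519.

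The difference of H from N was compared across loci with that of 50CSH from 50CSN, which share no library, to ask whether purebred differences recur between crosses of opposite sire breed. Across the 13871 loci Pearson's r was 0.090 and Spearman's rho was -0.01. Without the loci listed at 0 in any library, left out after the data were seen, Pearson's r was 0.004. The block of chromosome 23 between 28 and 29 Mb held 7 lower loci for H against N, more than in any shuffle. It held 4 for 50CSH against 50CSN, within the range of the shuffles, which treat loci of one span as independent.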

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

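The restrictions to loci above 0 in all libraries and to loci with an Ensembl transcript ID, and removal of the density trend, were chosen after the data were seen. Under 19 other settings, 119 of 186 recomputed values stayed within their limits, a count within 1.5 times the main one or a value inside its 95 percent interval, and 67 did not. Median-of-ratios scaling and quantile normalization moved no count or value beyond these limits. For pairs of libraries the limits apply to totals, not to direction, and the median-of-ratios factors were only 0.979 to 1.023. Quantile normalization moved the share of higher loci by up to 11.8 points, for 50CSH against N. It took the median log2 difference of 50CSN from N from -0.039 to 0.035. Counts of loci at least 2-fold apart are given in the order H vs N, 50CSH vs 50CSN, 75C vs 50CSN, 75C vs 50CSH, 75C vs N, 75C vs H, 50CSN vs N, 50CSN vs H, 50CSH vs N and 50CSH vs H. With a pseudocount of 0.1 they were 804, 763, 882, 901, 1043, 858, 1361, 1330, 1399 and 1334, since low loci then count more. With a mean of at least 5 FPKM, which tests fewer loci, they were 232, 190, 267, 270, 332, 267, 429, 442, 442 and 446. Per transcript, with 26826 values, they were 2388, 2426, 3111, 3082, 2775, 2462, 3812, 3877, 3810 and 3895. Among loci with an Ensembl ID, again fewer, they were 259, 196, 257, 268, 382, 285, 504, 478, 514 and 508. The count outside the purebred range, 240, was 374 with a pseudocount of 0.1, 153 with a mean of at least 5 FPKM, 720 per transcript and 44 with a margin of 2-fold, and 343 to 742 when 1 crossbred was left out.

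By limma, 4 loci passed the adjusted threshold, against 2 with a mean of at least 5 FPKM, 8 per transcript, 0 among loci above 0 in all libraries (3102 at an unadjusted p of 0.05), 8 with robust fitting, 12 at an adjusted p of 0.1, and 3 to 21 when 1 library was left out. Of the 4 loci, 2 passed in each fit without 1 library. Without N 9 passed and without H 21, fits in which the lone purebred is assumed to vary like the crossbreds. The locus on chromosome 12 passed in all 16 locus-level fits that tested it, and that on Un.004.2 in 13 of 14. With both purebreds in the fit, the adjusted p by limma was 0.00061 to 0.035 for the first and up to 0.051 for the second. The locus on chromosome 19 passed in 9 of 15, up to 0.15 with both purebreds. That on chromosome 18 passed in 9 of 17, up to 0.23 with both purebreds, its log2 difference staying between -2.04 and -1.80. The loci on chromosome 12, Un.004.2 and chromosome 19 are listed at 0 in all crossbreds. Every fit that tested them reuses these zeros, which have little or no spread. Passing in many fits therefore does not show that the zeros are true levels. The count at an unadjusted p of 0.05, 3014, ranged over the fits without 1 library from 1753 without N to 3669 without 75C, with 1900 without H and 1927 without 50CSH. It was 3897 with no filter on low values and 3738 per transcript, where more values were tested.

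The median position of 75C was 0.568 per transcript, that of 50CSN 0.454, and that of 50CSH 0.467. The position of 50CSH was 0.595 with no filter and 0.681 at loci 4-fold apart between H and N. The share of loci with 75C farther toward H than 50CSN was 56.6 percent per transcript and 68.4 percent at loci 4-fold apart. The share farther toward H than 50CSH was 58.2 percent at loci 4-fold apart. There the exact binomial 95 percent interval, 48.4 to 67.5, includes an even split. Pearson's r between H - N and 50CSH - 50CSN was 0.107 with a mean of at least 5 FPKM, 0.040 per transcript, 0.058 among loci with an Ensembl ID and 0.0036 among loci above 0 in all libraries, and Spearman's rho was 0.0054 per transcript. Where no cause is given, the cause was not tested. No paired analysis was possible because each population has 1 library. The alternatives for gene lists were not run, because no list member could be matched to the files. Read depth is unknown beyond ratios between libraries, so it cannot be said at which level a value of 0 excludes expression.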

Other observations

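The removal of the density trend was set as a test before its result was seen, and all other tests below were chosen after the patterns were seen. The transcript that held most of a locus was compared at 6963 loci with several transcripts and at least 5 FPKM in every library. It was the same in all 5 libraries at 75.4 percent of them. In 178 loci 50CSN and 50CSH shared one main transcript while N, H and 75C shared another. On chromosome 13, at a locus of 5 transcripts in the span from 54710813 to 55860965, one transcript held 70.7 percent of the locus in 50CSN and 75.4 percent in 50CSH and was listed at 0 in N, H and 75C, where another transcript held 69.6, 75.3 and 71.6 percent. The level of the whole locus was 174 FPKM in N, 202 FPKM in H, 194 FPKM in 75C, 165 FPKM in 50CSN and 146 FPKM in 50CSH. On chromosome 3, from 20236547 to 20242468, one of 2 transcripts held 100.0 percent in both 50 percent crosses and 14.3 percent in N, 3.67 percent in H and 29.2 percent in 75C. On chromosome 22, in the span from 52015195 to 52208060, one of 3 transcripts held 73.5 percent in 50CSN and 74.5 percent in 50CSH and under 1 percent in the other 3 libraries.

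This grouping of the 50 percent crosses gave 178 loci, and the highest of the other splits of the 5 libraries into 3 and 2 was 90, for the crossbreds against the purebreds. With 10 splits, of which 1 gave as many, the splits are too few for a share under 0.05. The main transcript also differed in 1 library alone, at 152 loci for N, 144 for H, 119 for 75C, 197 for 50CSN and 175 for 50CSH. The 50 percent crosses share their ancestry, and the labels give no day or batch of library preparation. The FPKM model also divides reads between the transcripts of a locus. Effects of descent, of handling and of that division all remain open and untested.

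The crossbred and purebred libraries differed at 3014 loci at an unadjusted p of 0.05 by limma, and the crossbred minus purebred difference fell with local locus density. The highest of the other splits, 50CSN and 50CSH against the rest, gave 2645. Of the 10 splits, 1, the real one, gave as many, too few splits for a share under 0.05. Past an adjusted p of 0.05 by limma the real split did not rank first. It gave 4 loci, against 7 for 50CSN and 50CSH and 6 for N and 75C. The average trend of each library with local locus density is argued against as the whole cause. On the 12972 loci with a density, 2906 reached an unadjusted p of 0.05 by limma before the trend was removed. After removal 2850 did, 4.39 times the nominal number by chance, which takes the libraries of a group as replicates. Only the average curve of each library was removed, so effects that differ between loci of the same density remain. By the relative estimate N and 50CSN were the deepest libraries, yet they lay farthest apart in the densest of 5 groups of loci. The median was 0.187 over the differences at each locus (95 percent interval over loci 0.165 to 0.209). For 50CSN that estimate rests on 148 of 2521 low loci near the most frequent ratio. By transcripts above 0 the 50 percent crosses were lowest, 47214 in 50CSN and 46652 in 50CSH, against 48332 in N, 47590 in H and 47435 in 75C. Sequencing depth as the cause of the density trend therefore remains open. The levels did not follow a simple order by Holstein share, since both purebreds lay above both 50 percent crosses in the densest group. That gap is part of the pattern itself, and each population has 1 library. An effect of Holstein share therefore cannot be excluded. The smallest gap was 0.109 between library medians of the distance from the mean of the 5 libraries. A first-cross effect, the animals sampled, cell composition and library preparation may each contribute and were not tested.

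At 127 loci a library stood at 10 FPKM or more while another was listed at 0. Of these, 41 were above 0 in 1 library alone, among them 14 in N with values up to 3865 FPKM and 11 in 75C with values up to 3189 FPKM. Reads divided equally between near-identical copies would leave equal values at several loci, and 3.15 percent of the 127 had one equal in every printed digit to that of another locus. Of the 127, 61.4 percent shared their span with another kept locus, against 27.4 percent of all kept loci and 31.1 percent of those with a single transcript, so unequal division of reads within a span remains open. At 0 in N alone, H alone, both purebreds, all 3 crossbreds or both 50 percent crosses were 13.4 percent. These are 5 of 30 possible patterns, or 16.7 percent of them. At 0 in exactly the 3 crossbreds were 2 loci, and other sets of 3 libraries gave up to 6. Other patterns can follow descent too, such as the 14 loci above 0 in N alone. With 1 library for each population an effect of descent and one of the single library cannot be told apart. A single transcript model was present at 96.9 percent, against 27.0 percent of all kept loci, but a sum over several transcripts is 0 only if all of them are, so the choice of loci listed at 0 raises that share whatever the cause, and unstable estimates at single transcripts remain open.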
